A study of Homo sapiens with 6 samples.

How the data were processed

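RNA sequencing was done on 6 libraries of PC9OR cells, 3 labelled NC and 3 labelled si-GLMP. Per the labels' protocols, RNA was extracted with Trizol, its integrity was checked on a Bioanalyzer, and Illumina mRNA libraries were made. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the 3 replicates of a group were separate cultures or transfections, so the p-values measure the spread between these libraries, which may be technical.

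The authors deposited a table of read counts per gene, with Ensembl gene identifiers and gene symbols. The values were whole numbers that summed to a different total in each library, and no normalization had been applied. HISAT2 and GRCh38 are named in the submitters' processing notes, with no version. The counting tool, the annotation release and the strand setting are not given in the sources used here. Without strand, reads of overlapping genes on opposite strands cannot be told apart. Genes with near-identical copies can gain or lose reads by the way shared reads were counted. This applies to AKR1C2 and AKR1C3, SPRR1A and SPRR1B, KRT81, PDZK1, the ribosomal protein genes and the mitochondrially encoded genes, whose values are uncertain to that extent.

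The table held 60664 genes, and all 6 of its count columns were matched to a sample by title, with 0 columns left over. Symbols were those of the table, and 20055 identifiers had none. Symbols of the gene lists that the table did not hold were matched through gene identifiers, and 60463 of the identifiers were found in the reference list of gene names. Library totals ran from 19896875 to 22372878 counts. A count of 3 corresponded to between 0.134 and 0.151 CPM (reads per gene scaled to a common library total), which was taken as the floor of detection. Exact Poisson 95% intervals of single counts cover counting error only, since the reads carried no molecular identifiers in the sources used here.

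Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10, which left 15900 genes with at least 99.84% of the counts of each library. Libraries were scaled by TMM factors, which lay between 0.9639 and 1.018. Dispersions and quasi-likelihood fits were robust, and the si-GLMP and NC groups were compared by the quasi-likelihood F test with the group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and 0.05 was the threshold. Here "edgeR adjusted p" means that value. Standard errors of log2 fold changes were computed as the fold change divided by the square root of F. Log2 fold changes are given ± standard error, and levels, in CPM scaled by TMM, as mean ± SD. The biological coefficient of variation was 6.91%.

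Before the data were examined, 28 gene lists were fixed, together with the tests and the alternatives. The lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation between genes of 0.01, and adjustment over the lists. A list needed 5 tested genes, so 27 lists were tested. Camera compares the genes of a list with all other genes. Each list was also tested with an estimated correlation and with fry, which asks whether the genes of a list move one way and makes no comparison with other genes. Members past the threshold were counted after adjustment over all genes and after adjustment over the list alone.

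The genes named in the text were also chosen by a rule fixed before the data were examined. The rule took GLMP, the genes MFSD1, RHOA, EGFR, TFEB, SQSTM1 and MAP1LC3B, and the 10 largest positive and 10 largest negative log2 fold changes. Those 20 had to have an edgeR adjusted p under 0.05, a symbol, a mean of at least 100 counts in the higher group, and no overlap in CPM between the groups. Up to 4 members of each list with the smallest adjusted p were added, which gave 134 genes in all. Of the fixed lists and named genes, 1 list, the genes added for it alone and 1 further gene are not reported here. Genes outside this rule are marked as chosen after their values were seen.

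The statistics were tested on simulated data drawn from the NC means and the sizes of these 6 libraries, with 15523 genes. Of 50 genes changed at each fold, 23 were recovered at 1.3-fold, 35 at 1.5-fold, 42 at 2-fold and 47 at 3-fold, and 4 unchanged genes were called. A list of changed genes was recovered, and 0 of the other lists were called. Genes were drawn independently, so this cannot show how often camera calls lists of correlated genes.

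Alternatives fixed before the data were examined were RLE and upper-quartile scaling, no filter on low counts, a filter of 1 CPM in 3 libraries, each library left out in turn, the replicate number as a block, DESeq2 1.42.0 and limma-voom. An absolute log2 fold change over 1 was a further one. Removal of a smooth trend on GC content and transcript length from each library, and removal of the mitochondrially encoded genes, were added after the data were seen. Transcript sequences, 3′ untranslated regions and coordinates were taken from the GENCODE 29 annotation of GRCh38. For the scan of 3′ untranslated regions, each of 16135 heptamers present in at least 100 regions was scored. The score was the difference in log2 fold change between genes with and without the heptamer, after adjustment for the length and GC content of the region. Scores were scaled by their own spread and p-values were Bonferroni corrected. In simulated data a shift of -0.1 on the log2 scale was recovered in 20 of 20 simulations and a shift of -0.05 in 15 of 20, and 2 of 20 simulations with no shift gave a call. The mean residual log2 fold change of genes with the heptamer was -0.0528 for CCAAGGA and -0.0267 for TTTCTCT, and no shift as small as the latter was simulated. The simulated heptamers were also present in fewer regions than TTTCTCT, so the recovery rates do not describe its result. Fold changes were shuffled between genes in the simulations. The rate of false calls therefore leaves out any real link between region content and fold change.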

Results

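The series asked which transcripts change in PC9OR cells, a lung cancer line, when GLMP is knocked down. PC9 is a human lung adenocarcinoma cell line with an activating EGFR deletion. The series title links GLMP to resistance against EGFR tyrosine kinase inhibitors, autophagy and the RhoA pathway. GLMP encodes a glycosylated membrane protein of the lysosome, the partner of the transporter MFSD1. Counts per gene were given for 3 NC libraries, the control of the knockdown, and 3 si-GLMP libraries. Total counts were 19896875, 21231466 and 22372878 in NC replicates 1 to 3, and 20527137, 21041277 and 20313899 in si-GLMP replicates 1 to 3.

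GLMP (ENSG00000198715) was strongly reduced in each si-GLMP library. Its counts were 309, 344 and 347 in the NC libraries, and 82, 61 and 65 in the si-GLMP libraries. The level was 15.9 ± 0.796 CPM (TMM-scaled) in NC and 3.34 ± 0.590 CPM in si-GLMP (SD, n = 3 each), a decrease of 79.0%. The log2 fold change was -2.25 with a standard error of 0.14 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.16e-18). GLMP lies on chromosome 1 of GRCh38, from 156290089 to 156295689 on the minus strand. Its exons share 607 bases, 17.5% of its exonic length, with TMEM79 on the opposite strand. TMEM79, chosen after its values were seen, had a log2 fold change of 0.49 (edgeR adjusted p = 9.95e-05).

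**Figure D1:**
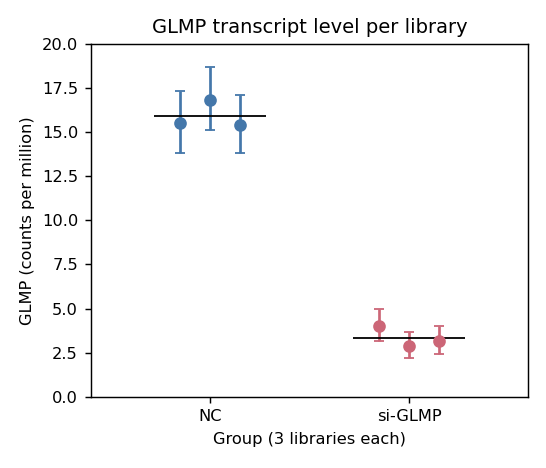
GLMP level in each library, in CPM on a linear axis, with exact Poisson 95% intervals of the counts as bars and the group mean as a line. The 3 si-GLMP libraries lie between 2.88 and 4.01 CPM and the 3 NC libraries between 15.4 and 16.8 CPM.

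The change reached well beyond GLMP. Of 15900 tested genes, 1910 were higher and 1802 lower in si-GLMP at an edgeR adjusted p under 0.05, together 23.3% of the tested genes. Most changes were small, with a median absolute log2 fold change of 0.39 among these genes. An absolute log2 fold change over 1 was met by 175 higher and 129 lower genes. The first principal component separated the groups and held 44.8% of the variance. The CPM values of the groups did not overlap in 36.5% of the tested genes, where chance gives 10%.

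The 10 largest rises by the naming rule ran from 1.56 to 2.22 on the log2 scale. S100A9 (ENSG00000163220), a calcium-binding protein of inflamed epithelia, rose from 8.70 ± 1.85 to 40.6 ± 5.13 CPM (SD, n = 3 each), a log2 fold change of 2.22 ± 0.12 (SE; edgeR adjusted p = 1.95e-16). HRNR, which encodes the cornified-envelope protein hornerin, rose by 2.12 ± 0.12 on the log2 scale (edgeR adjusted p = 1.63e-20). SPRR1A and SPRR1B, precursors of the same envelope, rose by 1.78 and 1.74. These 4 genes lie on chromosome 1, with HRNR starting at 152212082 and S100A9 ending at 153361027. C3, the central complement component, rose from 23.6 ± 1.89 to 75.7 ± 5.64 CPM, a log2 fold change of 1.68 ± 0.08 (edgeR adjusted p = 2.27e-22). C1S, a protease that starts the classical complement pathway, rose by 1.66. ANGPTL4, an inhibitor of lipoprotein lipase, rose by 1.67, and HPD, an enzyme of tyrosine breakdown, rose by 1.82. The secreted phospholipase gene PLA2G2F rose by 1.74 and the actin-capping gene TMOD1 by 1.56. TMOD1 shares 45.0% of its exonic length with TSTD2 on the opposite strand.

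After GLMP, the largest fall among the named genes was in LANCL1 (ENSG00000115365; chromosome 2, 210431249 to 210477652), which encodes a glutathione-binding protein. It went from 37.8 ± 1.21 to 10.1 ± 1.76 CPM (SD, n = 3 each), a log2 fold change of -1.91 ± 0.10 (SE; edgeR adjusted p = 5.91e-21). KRT81, a hair keratin, had -1.75, CCN2, a matricellular growth factor, -1.44, LHFPL6 -1.41, and PPP1R14C, an inhibitor of protein phosphatase 1, -1.40. PDZK1, a scaffold protein, had -1.33, HEG1, a transmembrane mucin-like receptor, -1.31, and FBXO2, a ubiquitin ligase subunit that binds glycoproteins, -1.30. TGM2, a protein-crosslinking transglutaminase, fell from 543 ± 26.2 to 154 ± 55.7 CPM, with a log2 fold change of -1.82 ± 0.29 (edgeR adjusted p = 0.0146). The TGM2 call was lost in 4 of 6 leave-one-out fits, with edgeR adjusted p of 0.0542, 0.0572 and 0.0502 without NC replicate 1, 2 or 3, and 0.0633 without si-GLMP replicate 3. Its log2 fold change in these 4 fits lay between -1.85 and -1.70, and DESeq2 (adjusted p = 6.03e-08) and limma-voom (adjusted p = 8.78e-13) kept the call. With the replicate number as a block the TGM2 call was lost (edgeR adjusted p = 0.0584).

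**Figure D2:**
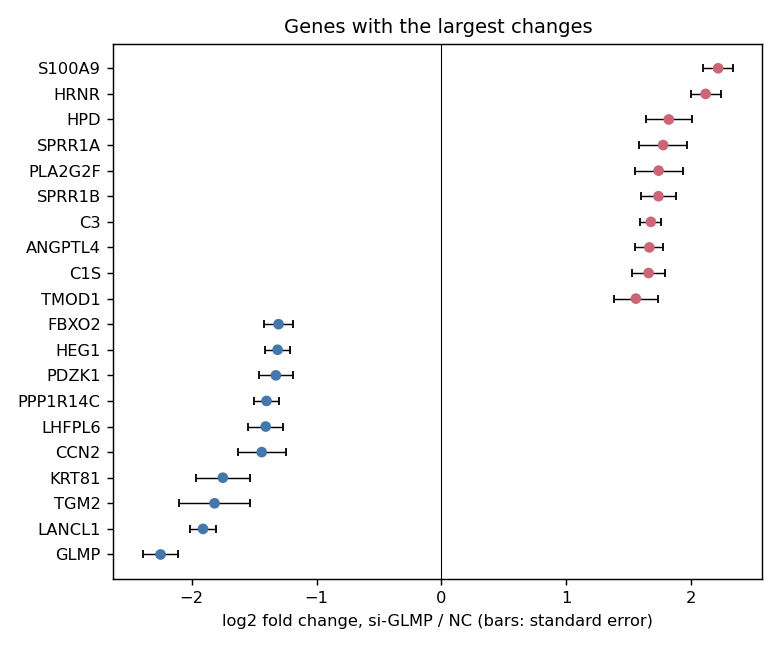
The 10 largest positive and 10 largest negative log2 fold changes by the naming rule, as points with standard errors, for si-GLMP against NC (n = 3 each). Values run from -2.25 for GLMP to 2.22 for S100A9.

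**Figure D3:**
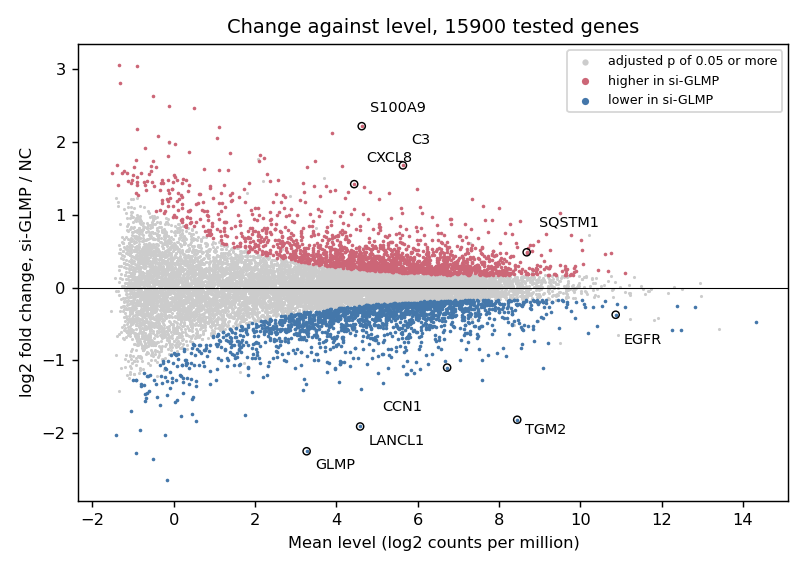
Log2 fold change of each tested gene against its mean level in log2 CPM, coloured by whether the edgeR adjusted p was under 0.05 and in which direction. Named genes are circled, among them EGFR with a log2 fold change of -0.37 and SQSTM1 with 0.49.

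Target genes of the transcription factors that respond to the actin cytoskeleton were lower in part. Of 24 tested YAP and TEAD targets, 15 were lower, 1 higher and 8 not past the threshold, with a median of -0.31; adjusted over the list alone, 17 were lower and 1 higher. CCN1, a matricellular protein, fell from 143.9 ± 1.01 to 67.1 ± 3.88 CPM (SD, n = 3 each), a log2 fold change of -1.10 ± 0.07 (edgeR adjusted p = 1.36e-18). CRIM1 had -0.69, the transcription factor gene TEAD1 -0.60 and DOCK5 -0.53. Camera gave an adjusted p of 1.09e-06, and the adjusted p was 0.0975 with an estimated correlation. Of 26 tested SRF and MRTF targets, 13 were lower, 1 higher and 12 not past the threshold, with a median of -0.24 and the same counts adjusted over the list alone. VCL, which encodes the focal-adhesion protein vinculin, had -0.74 ± 0.07 (edgeR adjusted p = 2.09e-13). CALD1, an actin-binding protein gene, had -0.66 and MYL9, a myosin light chain gene, -1.02. ITGA5, the fibronectin receptor subunit, was the 1 higher member, at 0.71. The camera adjusted p of this list was 0.000117, and the adjusted p was 0.422 with an estimated correlation. RHOA, the small GTPase gene fixed in advance, was not called, at 355.6 ± 13.2 CPM in NC and 326.5 ± 12.3 CPM in si-GLMP (SD, n = 3 each), with a log2 fold change of -0.12 ± 0.06 (edgeR adjusted p = 0.161). With the GC and length trend removed, an alternative added after the data were seen, RHOA had -0.15 (edgeR adjusted p = 0.0230).

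Most of the inflammatory genes tested rose. Of 22 tested inflammatory and NF-kB targets, 19 were higher, 0 lower and 3 not past the threshold, with a median of 0.55; adjusted over the list alone, 19 were higher and 1 lower. SOD2, the mitochondrial superoxide dismutase, rose from 63.6 ± 1.14 to 115.5 ± 14.5 CPM (SD, n = 3 each), a log2 fold change of 0.86 ± 0.08 (edgeR adjusted p = 3.12e-13). The neutrophil chemokine CXCL8 rose by 1.42 ± 0.12 (edgeR adjusted p = 2.56e-12), the signalling kinase gene IRAK2 by 1.01 and the adhesion molecule ICAM1 by 0.75. For the list, the camera adjusted p was 1.91e-09, and the adjusted p was 0.0540 with an estimated correlation. Of 24 tested interferon response genes, 13 were higher, 0 lower and 11 not past the threshold, with a median of 0.40 and the same counts adjusted over the list alone. BST2, a surface antiviral factor, rose by 0.43, the ubiquitin-like ISG15 by 0.85, IRF7 by 0.69 and IFIT1 by 0.96. By camera the adjusted p was 6.40e-05, and the adjusted p was 0.303 with an estimated correlation. Markers of leukocytes were near the floor. PTPRC had 6 counts summed over the NC libraries and 8 over the si-GLMP libraries, and LYZ and TYROBP had 0 in each library. Only 4 leukocyte markers could be tested and 1 passed, CSF1R, which rose from 17.7 ± 2.74 to 30.4 ± 1.94 CPM (edgeR adjusted p = 1.19e-08), a count of 1 also when adjusted over the list alone.

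Lysosomal genes were higher in part, and a few were lower. Of 42 tested lysosomal enzymes, 18 were higher, 3 lower and 21 not past the threshold, with a median of 0.17; adjusted over the list alone, 19 were higher and 4 lower. The aspartic protease CTSD rose from 70.4 ± 1.53 to 111.4 ± 5.42 CPM (SD, n = 3 each; log2 fold change 0.66 ± 0.07, edgeR adjusted p = 7.22e-11), and CTSL, a cysteine protease, rose by 0.56. CTSB, another cysteine protease, had -0.62 ± 0.07 (edgeR adjusted p = 7.82e-10), and GM2A, the ganglioside activator protein gene, -0.51. In the annotation, 41.7% of the exonic length of CTSD overlaps another gene on the same strand. Camera gave an adjusted p of 0.000126, and the adjusted p was 0.216 with an estimated correlation. Of 22 tested lysosomal membrane genes, 7 were higher, 2 lower and 13 not past the threshold, with 8 higher and 2 lower adjusted over the list alone. SCARB2, the receptor that carries glucocerebrosidase, rose by 0.42 and the tetraspanin CD63 by 0.37, and LAMP1, a main lysosomal membrane glycoprotein, had -0.33. Camera gave an adjusted p of 0.00924, and the adjusted p was 0.180 with an estimated correlation. MFSD1, the GLMP partner, rose from 23.3 ± 1.94 to 28.3 ± 1.48 CPM (log2 fold change 0.28 ± 0.09, edgeR adjusted p = 0.0202). Its edgeR adjusted p was 0.0612 without NC replicate 1, 0.113 without NC replicate 2, 0.0509 without si-GLMP replicate 1 and 0.0568 without si-GLMP replicate 2. Of 15 tested V-ATPase subunits of the proton pump, 4 were higher and 0 lower, and 4 higher and 1 lower adjusted over the list alone. ATP6AP1, an accessory subunit, had 0.30 (edgeR adjusted p = 0.000684). The V-ATPase list did not differ from other genes by camera (adjusted p = 0.244), and fry gave an adjusted p of 0.0174.

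The autophagy machinery, a theme of the series title, showed small changes in both directions. Of 55 tested members, 16 were higher, 4 lower and 35 not past the threshold, with a median of 0.07; adjusted over the list alone, 19 were higher and 5 lower. The cargo receptor SQSTM1 (p62) rose from 341.3 ± 24.9 to 477.8 ± 18.5 CPM (SD, n = 3 each; log2 fold change 0.49 ± 0.06, edgeR adjusted p = 3.45e-08). SQSTM1 shares 20.7% of its exonic length with MRNIP on the opposite strand. ATG5, needed for LC3 lipidation, rose by 0.43, and the fusion protein gene VAMP8 by 0.36, whereas MITF, a transcription factor for lysosomal genes, had -0.36. TFEB, its relative, was low and not called, at 1.65 ± 0.207 and 1.09 ± 0.386 CPM (edgeR adjusted p = 0.155). MAP1LC3B, which encodes LC3B, was not called (log2 fold change -0.21 ± 0.09, edgeR adjusted p = 0.0755), but passed without NC replicate 2 (0.0324) or without si-GLMP replicate 2 (0.0403). It also passed with the GC and length trend removed (edgeR adjusted p = 0.0321). The list just missed the threshold by camera (adjusted p = 0.0527), passed without NC replicate 2 (0.0378) or si-GLMP replicate 3 (0.0474), and had an adjusted p of 0.216 with an estimated correlation. It passed with no filter on low counts (0.0380), by fry (0.00904) and with the GC and length trend removed (0.0177).

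EGFR, the target of the inhibitors in the series title, fell from 2107 ± 135 to 1626 ± 62.5 CPM (SD, n = 3 each; log2 fold change -0.37 ± 0.06, edgeR adjusted p = 7.72e-06). EGFR carried TTTCTCT, a heptamer of the scan weighed below, 3 times in its 3′ untranslated region. Among the genes of its ligands, EREG rose by 1.39 ± 0.12 (edgeR adjusted p = 3.05e-10) and HBEGF by 1.11 ± 0.08 (edgeR adjusted p = 1.99e-17). The receptor gene EPHA2 rose by 0.51 and IGF1R had -0.65. In the list of EGFR family members, ligands and bypass receptors, 7 of 22 tested genes were higher, 7 lower and 8 not past the threshold, with 8 higher and 7 lower adjusted over the list alone. For the list, the camera adjusted p was 0.512, and fry gave an adjusted p of 0.0327. MAPK output genes also went both ways, with 5 of 20 higher and 4 lower (camera adjusted p = 0.567), and 6 higher and 4 lower adjusted over the list alone. DUSP5, an ERK phosphatase, rose by 0.46, and the ERK-induced transcription factor ETV5 had -0.44 and the pathway inhibitor SPRED2 -0.37.

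Hypoxia-inducible and glycolytic genes rose in part. Of 30 tested, 18 were higher, 0 lower and 12 not past the threshold, with a median of 0.25; adjusted over the list alone, 19 were higher. EGLN3, an oxygen-sensing prolyl hydroxylase, rose from 35.5 ± 1.78 to 91.0 ± 14.1 CPM (SD, n = 3 each; log2 fold change 1.36 ± 0.09, edgeR adjusted p = 1.46e-15). The glucose transporter SLC2A1 rose by 0.73, the angiogenic factor VEGFA by 0.70 and the lactate exporter SLC16A3 by 0.53. By camera the adjusted p was 1.09e-06, and the adjusted p was 0.216 with an estimated correlation. Of 13 mitochondrially encoded mRNAs, 6 were lower, 0 higher and 7 not past the threshold, with a median of -0.44, and 7 were lower adjusted over the list alone. MT-CO3 had -0.58 ± 0.08 (edgeR adjusted p = 1.83e-06) and MT-ND4L -0.41. The 13 mRNAs took 6.55%, 8.73% and 6.49% of the counts in NC replicates 1 to 3, and 5.18%, 5.49% and 5.31% in si-GLMP replicates 1 to 3. NC replicate 2 thus stood apart, and without it MT-CO1 moved from -0.47 to -0.30 on the log2 scale. The MT-CO1 call was lost without si-GLMP replicate 1 (edgeR adjusted p = 0.175), without si-GLMP replicate 2 (0.0744) and with the GC and length trend removed (0.0609). The call of the list held without it (camera adjusted p = 7.16e-05 with all libraries and 1.70e-05 without NC replicate 2). The adjusted p was 0.422 with an estimated correlation and 0.0502 by fry. Of 31 nuclear genes of oxidative phosphorylation, 2 were lower and 0 higher, with 0 of either adjusted over the list alone. Their camera adjusted p of 0.0482 rose to 0.0910, 0.181, 0.129 and 0.261 without NC replicate 1, NC replicate 3, si-GLMP replicate 2 and si-GLMP replicate 3, to 0.0559 with upper-quartile scaling, to 0.628 with an estimated correlation and to 0.251 by fry. The replicate number as a block ended this call too. Cytosolic ribosomal protein genes, with 1 of 34 higher and 2 lower, did not differ from other genes (camera adjusted p = 0.567), and adjusted over the list alone 0 were higher and 2 lower.

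Stress and detoxification genes were higher in part. Of 23 p53 targets, 9 were higher and 1 lower, and 10 and 1 adjusted over the list alone. GDF15, a stress cytokine, rose from 30.8 ± 1.27 to 65.7 ± 4.0 CPM (SD, n = 3 each; log2 fold change 1.09 ± 0.08, edgeR adjusted p = 2.98e-16), and the cell-cycle inhibitor CDKN1A rose by 0.78. Camera gave an adjusted p of 0.0150, and the adjusted p was 0.265 with an estimated correlation. Of 26 ER stress and ATF4 genes, 11 were higher and 2 lower, and 13 and 2 adjusted over the list alone. DDIT4, an inhibitor of mTORC1, rose by 0.93, the chaperone cofactor DNAJB9 by 0.76 and XBP1 by 0.36. In the annotation, 41.2% of the exonic length of DDIT4 overlaps an antisense gene. Camera gave an adjusted p of 0.00924 for this list, and the adjusted p was 0.422 with an estimated correlation. Of 26 apoptosis regulators, 8 were higher and 3 lower, and 9 and 3 adjusted over the list alone. The BH3-only gene PMAIP1 rose by 0.73, and BIRC3, an inhibitor of apoptosis also induced by NF-kB, by 0.99 (list camera adjusted p = 0.0193, adjusted p = 0.216 with an estimated correlation). Of 24 drug transporter and detoxification genes, 12 were higher and 1 lower, and 14 and 1 adjusted over the list alone. The aldo-keto reductase AKR1C2 rose by 0.74, AKR1C3 by 0.54, the thioredoxin reductase TXNRD1 by 0.46 and the exporter ABCC3 by 0.41. The AKR1C genes are close copies of each other, so their single values are uncertain. Camera gave an adjusted p of 0.000629, and the adjusted p was 0.0993 with an estimated correlation.

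Sterol genes fell in part. Of 27 genes of cholesterol synthesis and SREBP targets, 11 were lower, 4 higher and 12 not past the threshold, and 12 were lower and 4 higher adjusted over the list alone. DHCR7, the last enzyme of the pathway, had -0.49 ± 0.07 (edgeR adjusted p = 2.27e-07) and FDFT1, the squalene synthase gene, -0.35. For the list, the camera adjusted p was 0.0102, and the adjusted p was 0.444 with an estimated correlation and 0.0743 by fry. In S phase, 7 of 30 genes were lower and 2 higher, and 8 and 2 adjusted over the list alone, with RRM1 at -0.53 and RRM2, the other ribonucleotide reductase subunit, at 0.35. The S phase camera adjusted p was 0.0814, and 0.0379 without si-GLMP replicate 1; with the GC and length trend removed it was 0.0386. In G2 and M phase, 3 of 29 genes were lower and 0 higher, also adjusted over the list alone, with CENPF at -0.41 and the kinase gene AURKA at -0.39. That camera adjusted p of 0.0389 rose to 0.0910 without NC replicate 1, 0.0620 without NC replicate 2, 0.267 without si-GLMP replicate 1, 0.501 with an estimated correlation and 0.126 by fry.

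Epithelial markers rose in part, with 11 of 25 higher and 4 lower, also adjusted over the list alone. The tight-junction genes CLDN4 and CLDN3 rose by 0.59 and 0.78, the transcription factor gene ELF3 by 0.79 and the protease gene ST14 by 0.47. The camera adjusted p of 0.0474 rose to 0.0709, 0.0943, 0.146 and 0.0616 without NC replicate 1, NC replicate 3, si-GLMP replicate 1 and si-GLMP replicate 3. It was 0.0506 with the filter of 1 CPM and 0.443 with an estimated correlation. The call was also lost with the replicate number as a block. Mesenchymal markers went both ways, with 3 of 20 higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.728). COL1A1 rose by 0.91 and the matrix protein TNC by 0.34, and SNAI2 had -0.39. Their median was -0.08 and camera leaned down, while fry leaned up. Of 8 fibroblast and endothelial markers, 1 was higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.515). Their median was 0.09 with an upward camera direction, although their mean was slightly negative. Of 6 neuroendocrine markers, 2 were higher and 0 lower, also adjusted over the list alone (camera adjusted p = 0.185). These were ENO2, a glycolytic enzyme also on the hypoxia list, at 0.48 and the ubiquitin hydrolase UCHL1 at 0.31. Of 6 lung lineage markers, 1 was higher, FOXA1 at 0.56, and 1 lower, also adjusted over the list alone (camera adjusted p = 0.643).

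**Figure D4:**
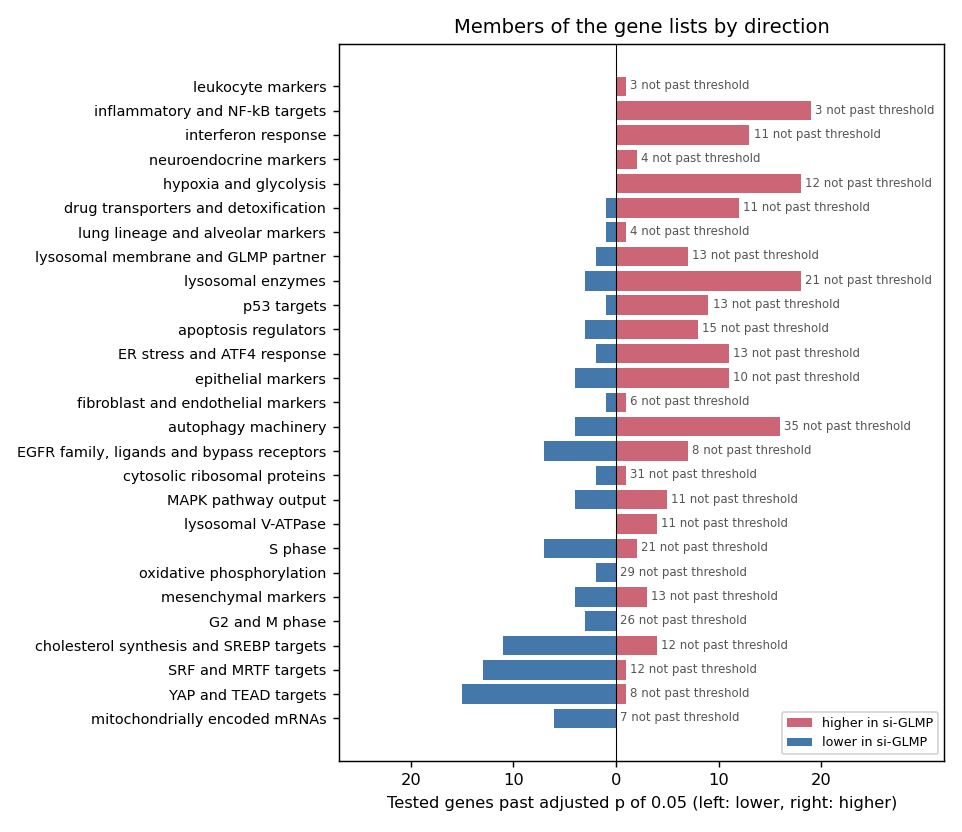
Number of tested members of 27 of the gene lists that were higher (right) or lower (left) in si-GLMP at an edgeR adjusted p under 0.05, with the number not past the threshold printed beside the bars. Lists are ordered by their median log2 fold change, from -0.44 for mitochondrially encoded mRNAs to 0.58 for the 4 tested leukocyte markers.

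By camera with the preset correlation, 17 of the 27 tested lists passed, 10 upward and 7 downward. With an estimated correlation 0 of the 27 passed. By fry 16 of the 27 passed, but these were not all lists that camera called. Sterol genes (fry adjusted p = 0.0743), G2 and M phase (0.126), oxidative phosphorylation (0.251) and mitochondrially encoded mRNAs (0.0502) passed by camera only. V-ATPase subunits (fry adjusted p = 0.0174), autophagy machinery (0.00904) and the EGFR family list (0.0327) passed by fry only.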

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

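Removal of the GC and length trend and of the mitochondrially encoded genes were chosen after the data were seen; the other settings were fixed before. No result changed direction in a called value under any setting run. The counts of 1910 higher and 1802 lower genes stayed within 1.5 times their value in each alternative except the fold threshold. DESeq2 called 1577 and 1542 genes and limma-voom 1845 and 1758. Leaving out 1 library gave 1482 to 1788 higher and 1283 to 1660 lower genes. An absolute log2 fold change over 1 left 175 higher and 129 lower genes. Among the alternatives for single named genes, 60 values lost their call and 19 gained one, with no change of direction. Gene lists were less firm, with 35 calls lost and 9 gained. Of 17 lists past the threshold, 0 passed with an estimated correlation, where the adjusted p was 0.216 for lysosomal enzymes and for autophagy. The estimates ran from -0.0351 for lysosomal membrane genes to 0.686 for mitochondrially encoded mRNAs. For inflammatory and NF-kB targets the estimate was -0.0113, below the preset 0.01, so a larger correlation did not end that call. The same held for drug transporters and detoxification (estimate -0.0135, unadjusted camera p from 0.00021 to 0.0147). It also held for lysosomal membrane genes (unadjusted camera p from 0.00377 to 0.0333). The calls lost in this setting therefore cannot be read as due to correlation between genes alone. The autophagy list gained a call with no low-count filter (0.0380), by fry (0.00904) and with the GC and length trend removed (0.0177), and ran from 0.0378 to 0.133 over the leave-one-out fits. The cause was not tested. The replicate numbers were not taken as pairs, a choice fixed in advance because no label says that a number marks a shared culture or day. Across genes, the deviations of samples with the same replicate number had correlations of 0.039, 0.026 and 0.001. NC replicate 3 correlated best with si-GLMP replicate 2 (0.010), so not every sample was nearest its own number. Principal component 2, with 16% of the variance, set replicate 2 apart in both groups, at -20.8 in NC and -15.4 in si-GLMP against 2.33 to 13.6 in the others. With the replicate number as a block, 2052 genes were higher and 1920 lower, and 15 lists passed. The block ended the calls of TGM2 (edgeR adjusted p = 0.0584), epithelial markers (camera adjusted p = 0.0755) and oxidative phosphorylation (camera adjusted p = 0.0546). GLMP had a log2 fold change of -2.25 in the block fit. Small effects can be missed, since 23 of 50 simulated genes were recovered at 1.3-fold.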

Other observations

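The test of leukocyte RNA, the test of both strands of the siRNA and the gene families of the next paragraph were chosen after the results were seen, as was the minimum of 100 regions per heptamer; the other tests were written before their results.

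Of 20 tested genes of the epidermal differentiation complex, 11 were higher and 0 lower. The choice of this family was prompted by S100A9, HRNR, SPRR1A and SPRR1B, so genes picked by the naming rule were left out of the family tests. Of the other 16 members 7 were higher, 43.8% against 11.6% of the other genes (Fisher's exact test, two-sided, p = 0.00128, adjusted p = 0.00384 over 3 families). The values of these 16 were also open to view when the family was chosen. The test therefore cannot decide whether the family rose as a set. The 7 higher members included S100A8 (log2 fold change 2.50 ± 0.43), SPRR3 (1.61) and FLG (1.63), which encodes filaggrin, while IVL, encoding involucrin, had 0.48 (edgeR adjusted p = 0.247). S100A8, SPRR3 and FLG were low in NC, at means of 0.271, 1.24 and 0.807 CPM. S100A8 had only 3, 9 and 5 counts in NC replicates 1 to 3, so the size of its rise is uncertain. S100A6 rose by 0.58 and S100A16 by 0.75, whereas S100A10 and S100A11 had 0.03 and 0.02. Of 12 genes of antigen presentation by HLA class I, 5 were higher and 1 lower, a family picked after its values were seen, for which no test is given. B2M rose by 0.25, HLA-E by 0.27 and TAPBP by 0.26, and the immunoproteasome subunit gene PSMB8 had -0.69. Of 14 complement genes, 3 were higher, C3, C1S and C1RL, and 1 was lower, SERPING1 at -0.72, and without C3 and C1S 1 of 12 was higher (exact p = 1.0).

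The first pattern weighed is the 1802 lower genes, which may come in part from partial matches of the siRNA to other mRNAs. The heptamer that went most with lower values in 3′ untranslated regions was CCAAGGA (across genes, n = 2378 with it, scaled z = -7.74, Bonferroni p = 1.67e-10), and a separate one was TTTCTCT (n = 4265, scaled z = -5.79, Bonferroni p = 0.000112). TTTCTCT lies in the GLMP mRNA, as only 6.59% of heptamers do in most of its transcripts, and so does TCCTTGG, the reverse complement of CCAAGGA, starting 11 bases upstream. Together they span TCCTTGGCCGATTTCTCT in the coding part of exon 3 of 6 of ENST00000362007.5 (chromosome 1, 156294476 to 156294493, minus strand). Seeds of both strands of 1 duplex would lie in this way. A pair within 25 bases in this arrangement has a chance of 0.000297 if all heptamers are taken as equally likely. The arrangement was chosen after the results were seen. Lower calls were 9.11% of genes with neither heptamer, 20.9% with CCAAGGA, 18.9% with TTTCTCT and 25.8% with both. After matching on region length, the excess was 25.3% of the lower calls in scanned genes. Either heptamer was present in 8 of the 9 largest named falls after GLMP, against 5569 of 12769 scanned genes. LANCL1 carried CCAAGGA 2 times and TTTCTCT 6 times, and EGFR carried TTTCTCT 3 times. HBEGF and EREG, which rose, carried 1 heptamer each. Both heptamers were picked from these same fold changes, so these shares may be too large and are not separate evidence.

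With the GC and length trend removed, 92.95% of the lower and 95.97% of the higher genes were still called, so that trend is not a likely source of them. The 10 splits of the 6 libraries are too few for a share under 0.05; the real split, 1 of 10, gave 1910 higher and 1802 lower genes, and the highest other split gave 0 of each by edgeR. On the side of higher genes the leading heptamer was TGGCTCA (Bonferroni p = 0.0236, across genes, n = 3397 with it), and an effect of the control siRNA cannot be told apart from a repeat effect, since 8 of the 10 leading heptamers there occur in the Alu consensus, against 3.10% of all heptamers.

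The second pattern is the fall of the YAP and TEAD list. Of its 24 tested members, 11 carried either of these heptamers, among them CCN1, CRIM1 and TEAD1. That share was close to the 5569 of 12769 scanned genes. CCN2, also on this list (log2 fold change -1.44), carried neither. Of the 13 members with neither heptamer 7 were lower and 1 higher, with a median of -0.23, and the 11 members with either had -0.49. The members with neither had camera p = 0.000581 with the preset correlation but p = 0.0849 with an estimated correlation, so matches in their own 3′ untranslated regions are an unlikely sole source only under the preset one. The whole list had adjusted p = 0.0975 with an estimated correlation. A loss of GLMP, and indirect effects of genes lowered by the siRNA itself, both stay open, and 1 control and 1 knockdown group cannot separate them.

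The third pattern is the rise of inflammatory and interferon genes. RNA from leukocytes is not a likely source, since PTPRC, CD3D, CD3E, LYZ, TYROBP and AIF1 together reached 0.323 CPM in si-GLMP and 0.270 CPM in NC, while CXCL8 reached 31.5 CPM in si-GLMP. A response to the loss of GLMP and a response of the cells to the double-stranded RNA of one duplex over the other remain as untested explanations.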
